A study of Lactococcus cremoris subsp. cremoris MG1363 and Lactococcus cremoris subsp. cremoris NZ9000 with 2 samples.

How the data were processed

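Total RNA of MG1363 and NZ9000 was converted to cDNA, labelled with Cy3 or Cy5 and hybridised together, per the labels' protocols. There were 2 samples, CDM and GM17, with 2 arrays each. Per the file headers, NZ9000 carried Cy3 on 1 array of each medium (array 1) and Cy5 on the other (array 2). The protocol text for RNA extraction names other strains than those of this series, so the culture conditions it gives were not used. A free-text line of the GM17 sample names CDM, while its title and medium field name GM17, and the latter were followed. The labels do not settle whether the arrays of a medium held separate cultures, so these arrays were averaged and counted as 1 replicate.

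The deposited array files hold spot and local background intensity on a linear scale for each dye, for 5470 spots per array, 2 for each of 2735 probes. The image software and its filters are not given in the sources used here. On each array 265, 266 (CDM), 259 and 250 (GM17) spots had been taken out before deposit, which shows as an intensity of 0 in both dyes; they were left out. Their median net intensity, still given in the deposited files, was 30.7, 27.4, 43.6 and 24.5, against 1237, 1425, 470 and 228 for the spots kept, so these were dim spots. The authors' deposited table gives 1 value for each of 2542 probes and medium, all matched to probes of the arrays. Its scale, centring and direction are not stated. Against log2 ratios from plain background subtraction its values had a slope of 0.692 in CDM and 0.665 in GM17, near the natural log of 2 (0.693), with r of 1.00 and 0.996, so the deposited values were read as natural log ratios of NZ9000 over MG1363. The column medians were 0.01 and 0.01, and how the authors centred the values stays unknown.

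Each array was processed in R 4.3.3 with limma 3.58.1: background correction by normexp with an offset of 50, loess within the array (span 0.3, 4 iterations) fitted without the 24 probes of plasmid and nisin genes, and averaging of the duplicate spots of a probe. The sign of each log2 ratio was then turned to NZ9000 over MG1363 by the dyes in the file headers. A probe was called well above background where its foreground was at least 1.5 times its local background, because the array files give no background SD and name no empty or control spots. Where a strain was not well above background on either array, its signal was raised to a floor where it lay below it. The floor was the lowest signal among probes well above background, per dye channel after loess and Aquantile scaling. Folds limited by this floor are given as at least that size, and a higher floor would give smaller folds. Gene symbols and locus tags come from the probe names; 426 probes of the table also had a platform symbol, equal to that of the array files in 426 cases, and 2116 had none. Of the loci, 303 had more than 1 probe; probes were kept apart, except in gene lists, which used the mean of a gene's measured probes. Genome coordinates were not used here, and neighbours are given by locus number.

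The comparisons, the thresholds, the gene lists and the rule for named genes were set before the data were examined. In each medium a probe passed the size rule when its mean log2 ratio was at least 1 in size, both arrays reached 0.5 in that direction, and it was well above background in at least 1 strain on each array; no test was possible with 1 sample. The difference between media needed at least 1 log2 unit between the means and no overlap between the arrays of the media. The strain difference over both media was tested with lmFit and eBayes on 1 value per medium, with Benjamini-Hochberg adjusted p under 0.05, so a difference between the media counts as spread. Adjustment was planned over all probes tested, and adjustment over each gene list alone was not among the comparisons set in advance. Ratios of the media were correlated across probes. For 28 gene lists the median log2 ratio was set against 10000 random lists matched on mean intensity in 20 bins. Named probes are pepN, nisR, nisK, ptcA, ptcB and ptcC, the 12 largest ratios in each direction that passed the size rule per medium, the 10 smallest p-values over both media, the 10 largest differences between media, and up to 4 genes per list with the largest mean ratio.

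The procedure was tested on simulated arrays made from the real intensities, backgrounds and array noise. In CDM, over 2440 probes, the size rule recovered 100% of changes of 3 log2 units, 98% at -1.5 and 94% at 1.5, and called 0 of 2240 unchanged probes. In GM17, over 1722 probes, it recovered 100%, 89.6% and 87.8%, and called 1 of 1525. The fit over both media, with equal changes simulated in both, recovered 100% of all sizes over 1635 probes and called 10 of 1438 unchanged probes. Noise was drawn independently for each probe with the same SD at every intensity, and no gene-specific dye effect was simulated. More probes were measured than on the real arrays (2433 in CDM, 1462 in GM17, 1402 in both). These shares therefore describe the simulated arrays only. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

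Alternatives fixed in advance were no background correction, plain subtraction, median centring, print-tip loess (span 0.4), Aquantile scaling, a signal in both strains, no filter on dim probes, the authors' deposited table, leaving out each array, limma on single arrays with and without a dye term, and a threshold of 1.5-fold. Those added after seeing the data were detection against the plasmid and nisin probes, the deposited table without a filter, normexp with an offset of 0, leaving out the probes of CDM from the correlation, and leaving out each array for gene lists, with random lists drawn on the array kept, and gene lists with plain subtraction, print-tip loess and random lists drawn in each setting. Probes of plasmid and nisin genes were left out of counts and lists. Lists of phage genes and transposases need gene descriptions, which were not used here.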

Results

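Gene expression was compared between 2 strains of Lactococcus cremoris on 2-colour DNA arrays. MG1363 is a plasmid-free laboratory strain. NZ9000 was derived from it by placing nisR and nisK, the regulator and sensor genes of the nisin system, in pepN, the gene of aminopeptidase N. The strains were grown in 2 media, CDM, the usual abbreviation for a chemically defined medium, and GM17, the usual abbreviation for M17 broth with glucose. Each medium was represented by 1 sample hybridised on 2 arrays with the dyes swapped, and all ratios are given as NZ9000 over MG1363. Values are the mean log2 ratio ± SD over the 2 arrays of a medium. The labels do not say whether these arrays held separate cultures, so the SD may be technical and the arrays counted as 1 replicate.

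Each array held 2711 probes for 2358 chromosomal loci. In CDM the median spot intensity was 1768 and 1555 for NZ9000 over local backgrounds of 154 and 154, and 1079 and 1626 for MG1363 over 112 and 175. In GM17 it was 871 and 482 for NZ9000 over backgrounds of 462 and 306, and 904 and 935 for MG1363 over 350 and 628. A probe was counted as measured when it was well above background in at least 1 strain on both arrays, which 2433 probes (89.7%) were in CDM and 1462 (53.9%) in GM17. The difference between the turned arrays, divided by 2, had an SD of 0.22 log2 units in CDM and 0.31 in GM17, and it reached 1 for 0 and 7 probes. Across probes, which are not independent replicates, the 2 arrays correlated with r = 0.664 and rho = 0.171 in CDM, and with r = 0.329 and rho = -0.0919 in GM17. The number of arrays limits the precision of every value below.

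The locus altered in NZ9000 was examined first. Probe mg8659 of pepN (llmg_0319) gave -4.74 ± 0.06 in CDM, a 26.8-fold lower signal in NZ9000, and -2.48 ± 1.06 in GM17, where NZ9000 was well above background on 1 of 2 arrays and the ratio is uncertain in size. The other pepN probe, MG1132, gave -0.76 ± 0.03 and 0.18 ± 0.41, so the probes of this gene disagreed. The signal of nisR and of nisK was not well above background in either strain in either medium, so pepN alone checked the strain labels. It was the only measured member of the 3 strain construction genes, with gene means of -2.75 in CDM and -1.15 in GM17.

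In CDM, genes for maltose and starch use were lower in NZ9000 along a run of 10 neighbouring locus numbers, from malG (llmg_0737) to malR (llmg_0746). The maltose phosphorylase gene mapA was 51.9-fold lower by probe MG1079 (-5.70 ± 0.05) and 33.3-fold lower by probe MG1080 (-5.06 ± 0.29). The alpha-amylase gene amyY gave -5.37 ± 0.09, dexA -5.19 ± 0.18, the maltose acetyltransferase gene maa -4.45 ± 0.27, the alpha-glucosidase gene agl -4.21 ± 0.01 and dexC -3.91 ± 0.81. The maltose transporter genes malE and malF gave -3.68 ± 0.03 and -3.36 ± 0.16. At another place on the chromosome the amylopullulanase gene apu (llmg_1869) was 11.3-fold lower, with -3.49 ± 0.13. Numbered close to it, the glycogen phosphorylase gene glgP (llmg_1871) gave -3.29 ± 0.19 by probe mg5208, -3.03 ± 0.24 by mg8240 and -2.49 ± 0.15 by mg8239. Of the 19 measured members of the maltose, starch and trehalose list, 11 were lower and 0 higher by the size rule.

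The mannitol uptake genes mtlA, mtlR and mtlF and the fermentation genes pfl and adhE were also lower in NZ9000 in CDM. NZ9000 was not well above background on either array for the mannitol genes, so only bounds are given: mtlA (llmg_0022) was at least 8.41-fold lower by probe MG1406 and 4.19-fold by probe mg6770, the regulator gene mtlR at least 6.24-fold lower and mtlF at least 2.88-fold lower. The gene msmK, for the ATPase of sugar ABC transporters, was 4.92-fold lower with -2.30 ± 0.53. The pyruvate formate-lyase gene pfl was 4.38-fold lower with -2.13 ± 0.29, and the alcohol dehydrogenase gene adhE gave -1.02 ± 0.40 and -1.06 ± 0.75 by its 2 probes. Of 16 measured genes of other PTS and sugar uptake, 4 were lower, and of 24 genes of mixed acid and pyruvate metabolism, 2 were lower; no member of either list was higher.

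In the other direction, the cellobiose PTS gene ptcC (llmg_0440) was higher in NZ9000 in CDM with 4.74 ± 0.95, and the neighbouring phospho-beta-glucosidase gene bglA (llmg_0441) with 4.54 ± 1.18. For both, MG1363 was well above background on 1 of 2 arrays, so these ratios are uncertain in size. By contrast ptcA (llmg_0438) gave -1.12 ± 0.17, and ptcB was not well above background in either strain. Of 9 measured cellobiose and beta-glucoside genes, 2 were higher and 1 lower. The gene napC (llmg_0320), numbered next to pepN, gave 3.51 ± 1.22. The nuclease gene nucA gave 1.95 ± 0.05. Among the higher genes were ribonucleotide reductase genes, which formed no list of their own: nrdE gave 1.49 ± 0.75 to 1.57 ± 0.58 over its 3 probes, nrdI 1.57 ± 0.03, nrdH was 2.83-fold higher and nrdF gave 1.34 ± 0.28. None of the probes of these genes measured in GM17 passed the size rule there, with values from 0.29 (nrdF) to 0.81 (nrdE). Of the loci without a gene name, llmg_0281 gave 1.33 ± 0.07 and llmg_0641 1.23 ± 0.48.

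Altogether 56 of 2433 probes in CDM passed the size rule, 19 higher (17 genes) and 37 lower (32 genes) in NZ9000. With 1 sample in this medium there was no replicate test. In a limma fit over the single arrays, whose p-values measure only the spread between arrays, 48 of the 1402 probes measured in both media had an adjusted p under 0.05 in CDM, 13 higher and 35 lower, and 41 of these 48 were among the 56.

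**Figure D1:**
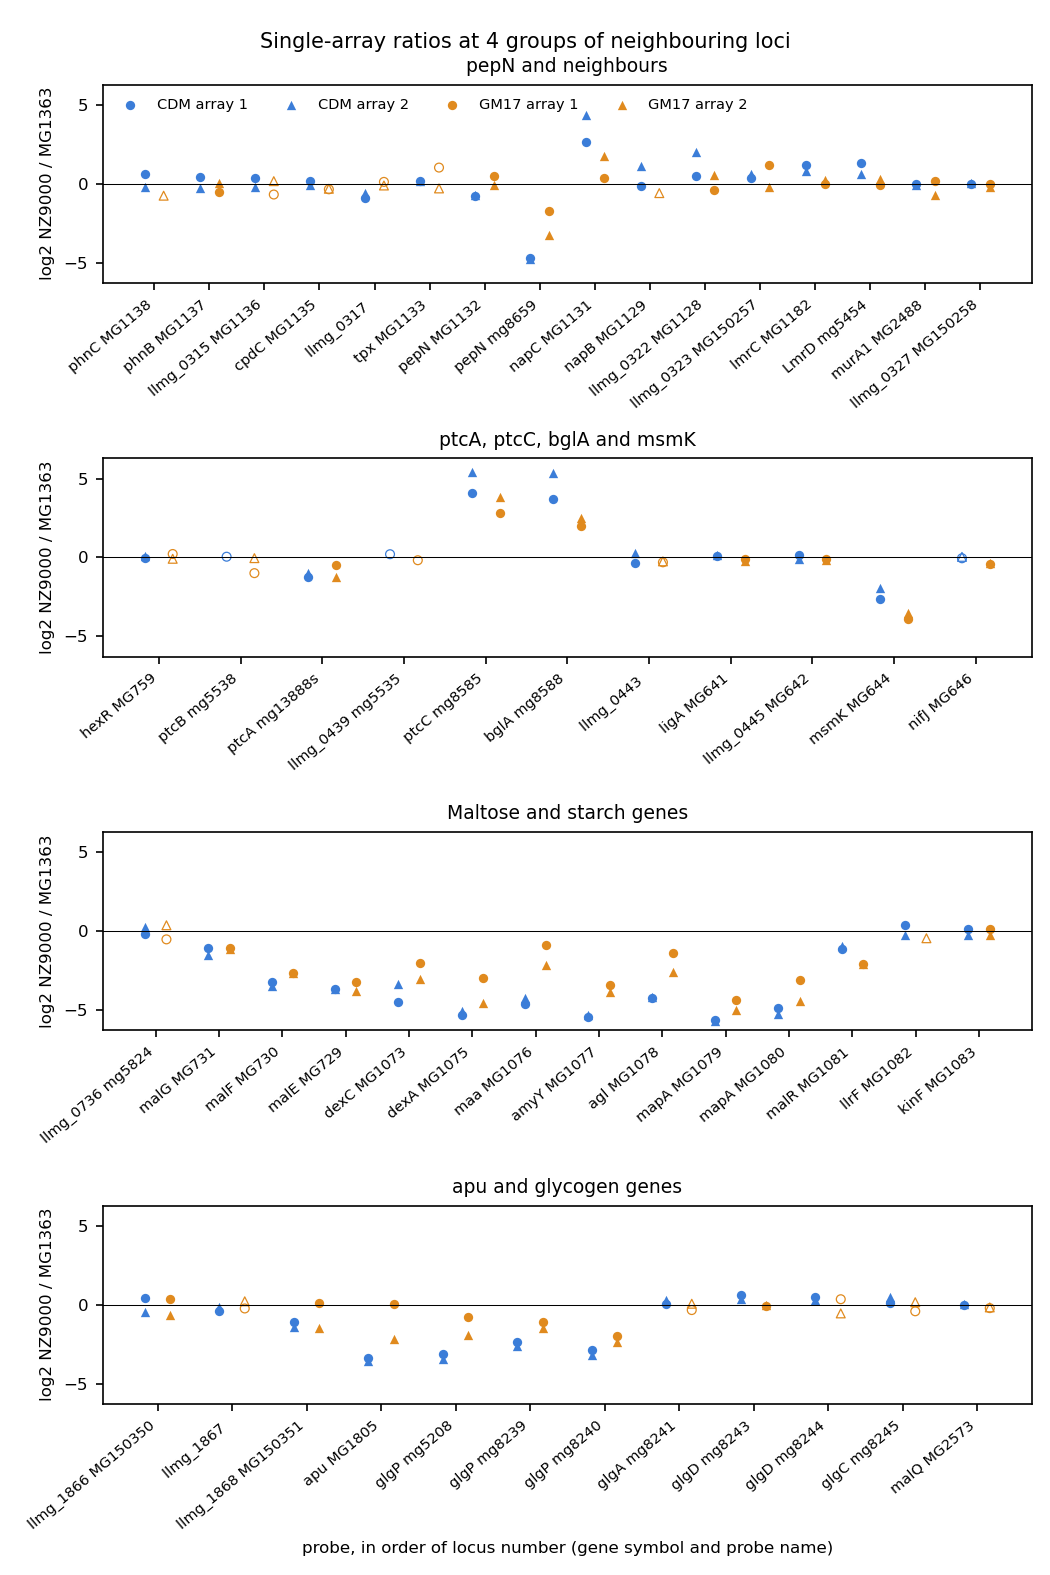
Log2 ratio of NZ9000 over MG1363 on each single array (vertical axis) for probes in order of locus number (horizontal axis) at 4 groups of neighbouring loci; circles are array 1 and triangles array 2 of CDM (blue) and GM17 (orange), and open markers are probes not counted as measured in that medium. The maltose and starch genes from malG to malR lie below 0 on all 4 arrays, while ptcC and bglA lie above 0 on all 4.

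In GM17 the same maltose and starch run was lower in NZ9000. The mapA probes gave -4.69 ± 0.41 and -3.79 ± 0.96, dexA -3.79 ± 1.11, amyY -3.65 ± 0.35, malE -3.53 ± 0.40 and malR -2.10 ± 0.01. Of 14 measured members of the maltose, starch and trehalose list, 11 were lower and 0 higher. The gene msmK was 13.2-fold lower with -3.73 ± 0.24, and pfl gave -1.30 ± 0.10. For glgP the values were -2.16 ± 0.26 by probe mg8240, -1.35 ± 0.81 by mg5208 and -1.30 ± 0.29 by mg8239. By probe mg6770 mtlA was lower, with -1.45 and -4.22 on its arrays. Its other probe, MG1406, gave -0.21 and -3.45 and did not pass. NZ9000 was not well above background on either array for these mtlA probes, so their ratios are uncertain in size. The gene ptcC was at least 9.93-fold higher in NZ9000, since MG1363 was not well above background, and bglA was higher with 2.25 ± 0.34. In GM17 MG1363 was well above background on 1 of 2 arrays for bglA. The same held for NZ9000 for malE, mapA probe MG1080 and glgP probe mg5208, so these ratios are uncertain. Where it passed on both arrays, NZ9000 could still be near background. It was 2.07 and 1.53 times background for mapA MG1079, 2.20 and 1.59 for amyY and 1.65 and 1.70 for dexA. The sizes of these ratios are uncertain too.

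In total 24 of 1462 probes passed the size rule in GM17, 4 higher and 20 lower, from 4 and 16 genes. All were also measured in CDM, and 20 of them passed there in the same direction, 2 higher and 18 lower. The 4 that did not pass in CDM were named after their values were seen. Higher were llmg_0945 (1.23 ± 0.01) and ps356 (1.01 ± 0.45). Lower were both probes of the trehalose 6-phosphate phosphorylase gene TrePP, with NZ9000 not well above background on either GM17 array. Probe mg8608 gave -0.53 and -2.37 on the arrays, and mg8606 gave -0.60 and -1.48, so both ratios are uncertain in size. The count rested on both arrays: without array 2 it was 104 probes, 82 of them higher, and with a signal well above background in both strains it was 13. Over chromosomal probes with a value on every array, GM17 array 1 correlated with the CDM arrays at r = 0.329 and 0.305. Array 2 did so at 0.453 and 0.577, so GM17 values without array 2 rest on the array less like those of CDM. A limma fit over the single arrays gave 28 probes with an adjusted p under 0.05 in GM17, 5 higher and 23 lower, and 24 of the 28 were the probes of the size rule.

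Gene lists were set against 10000 random lists of the same size and intensity in the same medium, and the range given below is the central 95% of these. In CDM the medians of 8 of 25 lists with at least 3 measured genes lay above that range and those of 9 below it. In GM17 this held for 1 and 3 of 23 lists. When each array was left out in turn and random lists were drawn on the remaining array, 6 of these 17 lists in CDM and 3 of the 4 in GM17 stayed outside the range on their side both times. Detection was then judged on the remaining array alone, so the genes of a list could differ. The dye effect of that array was also no longer cancelled. Of the lists within the range, 3 of 8 in CDM and 12 of 19 in GM17 changed sign with an array left out, so the signs of these medians carry no weight. Members of an operon are not independent, which the random lists do not allow for. The list of maltose, starch and trehalose use had the lowest median of these lists in both media, at -1.28 in CDM and at -2.05 in GM17. Without array 2 its GM17 median was -1.28, over 17 genes instead of 14. Other PTS and sugar uptake was at -0.41 and -0.32. Both lists were below the range in both media and with either array left out. The list of cellobiose and beta-glucoside genes lay within it, at -0.04 and 0.04, as did mixed acid and pyruvate metabolism, at -0.05 and 0.01.

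**Figure D2:**
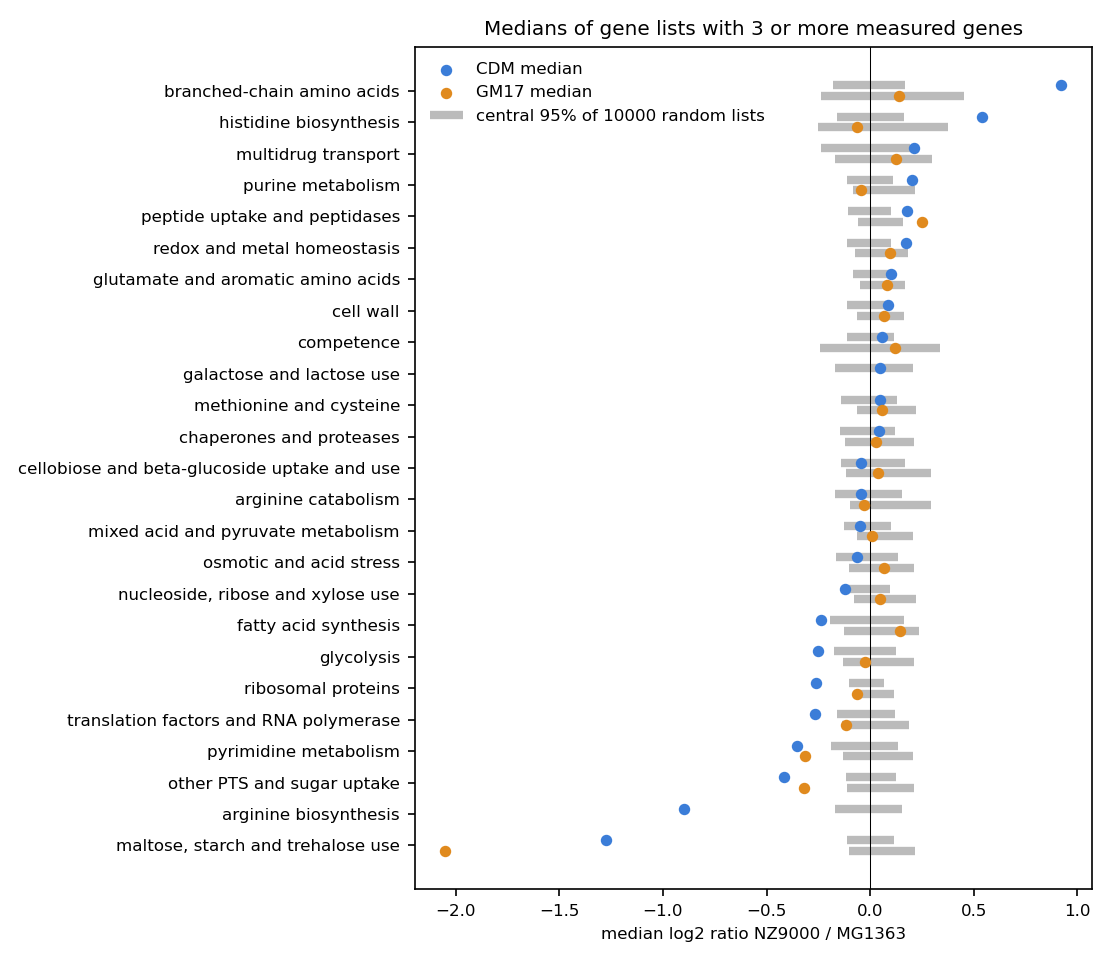
Median log2 ratio of NZ9000 over MG1363 (horizontal axis) for each gene list with at least 3 measured genes (vertical axis) in CDM (blue) and GM17 (orange); grey bars are the central 95% of 10000 random lists of the same size and intensity. The maltose list lies lowest in both media, and branched-chain amino acids and histidine biosynthesis lie highest in CDM, at 0.92 and 0.54.

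Genes of amino acid synthesis lay on both sides of 0 in CDM. Branched-chain amino acid genes had a median of 0.92, above the range with either array left out, with 4 of 11 measured members higher: leuA at 1.15, leuC at 1.10, and ilvD and ilvB at 1.02 each. Histidine biosynthesis had a median of 0.54, with hisZ at 0.99 and hisG at 0.91, although 0 of 11 members passed the size rule; the median was 0.83 without array 1 and 0.20 without array 2, the latter within the range. In the list of glutamate and aromatic amino acids 1 of 37 members was higher, the citrate synthase gene gltA at 1.05, and its neighbours citB and icd were at 0.91 and 0.82; the list's median was 0.10, above the range, but within it with either array left out. Arginine biosynthesis had a median of -0.90, below the range with either array left out, with 3 of 9 members lower, among them argG at -1.47 and argH at -1.36, and with argB, gltS and argF at -0.91, -0.90 and -0.87. Arginine catabolism, at -0.04, and methionine and cysteine, at 0.05, lay within the random range. In GM17 these lists had 3 or fewer measured members or lay within the range: branched-chain amino acids 0.14, histidine -0.07, arginine biosynthesis 0.11, arginine catabolism -0.03, glutamate and aromatic amino acids 0.08, methionine and cysteine 0.06. Without array 2 the GM17 median of the glutamate list was -0.24, below the range, over 38 genes instead of 22. Within the range, branched-chain amino acids were at 0.57 without array 1 (3 genes) and -0.29 without array 2 (9 genes). Arginine catabolism was at -0.19 and 0.21, over 10 genes each time.

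Genes of translation and central metabolism had smaller ratios. Ribosomal protein genes had a median of -0.26 in CDM, below the range, -0.34 without array 1 and -0.13 without array 2, both still below it, and -0.06 in GM17, within it, and 0 of 47 and 0 of 46 passed the size rule; examples in CDM were rplQ and rpsD at -0.64 and -0.63. Translation factors and RNA polymerase gave -0.27 and -0.12, glycolysis -0.25 and -0.03, and fatty acid synthesis -0.24 and 0.14, each below the range in CDM and within it in GM17. In CDM each of these 3 came within the range with an array left out: translation factors at -0.12 and fatty acid synthesis at -0.18 without array 2, and glycolysis at -0.054 without array 1. In GM17 translation factors were at -0.28 without array 1, below the range. With median centring the GM17 medians of ribosomal proteins and translation factors were 0.16 and -0.027, both below the random range of that setting, which was 0.18 to 0.35 and 0.013 to 0.31. Pyrimidine metabolism lay below the range in both media, at -0.35 and -0.31, with pyrC at -0.67 and -0.64. Without array 1 its CDM median was -0.12, within the range, and its GM17 median -0.53. Peptide uptake and peptidases lay above the range in both, at 0.18 and 0.25, with dppA at 0.60 and 0.33, but the GM17 median turned to -0.11 without array 2, within the range. No member of these lists passed the size rule.

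Purine metabolism was at 0.20 in CDM, above the range, and at -0.04 in GM17, within it, or -0.14 with median centring, below it. Without array 1 the CDM median turned to -0.087, within the range. Redox and metal homeostasis gave 0.17 and 0.10, with mntH at 0.74 and 0.28. The cell wall list gave 0.09 and 0.06 and multidrug transport 0.21 and 0.12, with lmrC at 1.02 and 0.11. These 3 lists lay above the range in CDM and within it in GM17. In CDM redox and metal homeostasis (0.12) and multidrug transport (0.026) came within the range without array 1, and the cell wall list (0.078 and 0.048) with either array left out. In GM17 redox and metal homeostasis was at 0.17 without array 1, above the range. Nucleoside, ribose and xylose use gave -0.12, below the range but within it without array 2 (-0.090), and in GM17 0.05, within it. Galactose and lactose use, at 0.05 in CDM with 2 genes measured in GM17 (0.24), chaperones and proteases, at 0.04 and 0.03, and osmotic and acid stress, at -0.06 and 0.06, lay within it. Competence, at 0.06 and 0.12, lay within it too, with nucA higher and coiA lower at -1.06 in CDM. Phage genes and transposases had no members that could be matched by symbol.

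The strain difference was then compared between the media. The gene maa gave -4.45 ± 0.27 in CDM and -1.51 ± 0.89 in GM17, agl -4.21 ± 0.01 and -2.00 ± 0.89, and amyY -5.37 ± 0.09 and -3.65 ± 0.35. The gene apu gave -3.49 ± 0.13 and -1.07 ± 1.56, and its GM17 arrays were at 0.035 and -2.18. For maa, agl and apu NZ9000 was well above background on 1 of 2 GM17 arrays, as was MG1363 for napC, bglA and argH, so the GM17 ratios are uncertain in size. In the other direction napC gave 3.51 ± 1.22 and 1.04 ± 0.98, and bglA 4.54 ± 1.18 and 2.25 ± 0.34. The arginine biosynthesis gene argH gave -1.36 ± 0.15 in CDM and 0.36 ± 0.24 in GM17. While most of these ratios were larger in CDM, msmK and malR were lower in GM17 than in CDM. By the rule for the difference, 31 of 1402 probes differed by at least 1 log2 unit with no overlap between the arrays of the media, 9 with a higher and 22 with a lower ratio in CDM.

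Absence of overlap alone was met by 403 of these 1402 probes (28.7%), while chance gives 33.3% for 2 against 2 arrays. A limma fit of the difference over the single arrays gave 9 probes with an adjusted p under 0.05, all 9 among the 31, and for 8 of the 9 one strain was well above background on only 1 of 2 GM17 arrays; with 1 sample per medium these p-values compare arrays, not media. Requiring a signal well above background in both strains left 16 probes, and leaving out array 2 of GM17 gave 152. No slide held both media, so slide and medium cannot be told apart.

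Across the 1402 probes measured in both media, the ratios in CDM and GM17 correlated with r = 0.734 and rho = 0.291. The 41 probes that passed the size rule in CDM, led by maltose and starch genes, pepN mg8659, ptcC and bglA, gave r = 0.90 and rho = 0.893. The other 1361 probes gave r = 0.259 and rho = 0.240. The split was made on the CDM values, which widens their spread in the first set and narrows it in the other. The difference between these correlations therefore comes in part from the split. Probes are not independent replicates, and without array 2 of GM17 the correlation over all probes was 0.375. Of the 56 probes of CDM, 15 were not measured in GM17, among them nucA, nrdI, argG, leuA and gltA, and 0 passed in opposite directions.

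**Figure D3:**
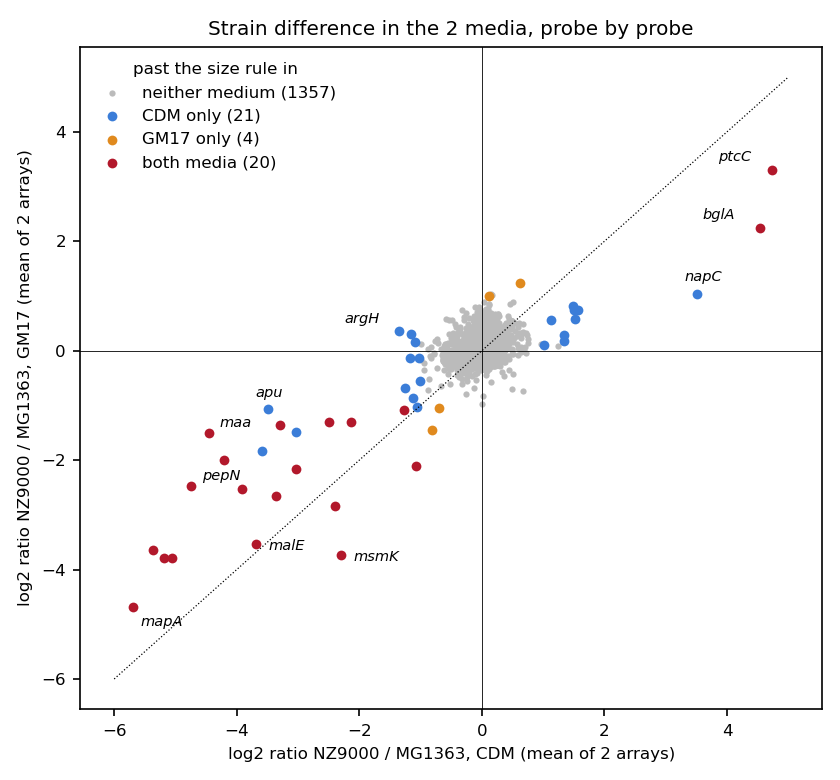
Mean log2 ratio of NZ9000 over MG1363 in CDM (horizontal axis) against GM17 (vertical axis), 1 point per probe measured in both media; colours mark probes that passed the size rule in both media (20), in CDM only (21), in GM17 only (4) or in neither (1357), and the dotted line marks equal ratios. The maltose genes lie at the lower left and ptcC and bglA at the upper right.

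A final comparison took both media together, with 1 value per medium. The maltose-binding protein gene malE was lower in NZ9000 on 4 of 4 arrays, with a mean log2 ratio of -3.60 (SE 0.12), although NZ9000 was well above background on 1 of 2 GM17 arrays, and was the only 1 of 1402 probes with a limma adjusted p under 0.05 (0.0192). The probes with the next smallest p-values were mapA MG1079 at -5.20 and mtlA mg6770, with limma adjusted p of 0.0637 and 0.0641, the latter with NZ9000 not well above background in either medium, so that no ratio is given. They were followed by malF, the other mapA probe, dexA, ptcC, glgP, malG and amyY. Adjustment over each list alone was not among the planned tests and does not correct for the number of lists. By it, 16 of 18 probes of maltose, starch and trehalose use had a limma adjusted p under 0.05, all lower, against 1 adjusted over all probes. These 16 include both TrePP probes, for which NZ9000 was not well above background in GM17.

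Adjusted over its own list, other PTS and sugar uptake had 4 of 12 probes under 0.05. Among these, both mtlA probes and mtlR had NZ9000 not well above background in either medium. The cellobiose list had 3 of 8 probes under 0.05 (ptcC and bglA higher, ptcA lower). The mixed acid list had 2 of 21 (pfl MG2361 and adhE MG266, lower), and strain construction 1 of 2 (pepN mg8659). Each of these lists had 0 when adjusted over all probes. The adhE probe MG265 and the pepN probe MG1132 did not pass. The remaining lists had 0. At an unadjusted p under 0.05 there were 117 probes, 58 higher and 59 lower. The count over all probes was 0 without background correction or with a signal required in both strains, and 44 when each array entered as its own value, so it depended on the setting.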

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

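The tests of technical explanations below were chosen after the results were seen; for the loci after pepN and for the slides they were also revised after a first outcome, which is given. The limma fit over single arrays was planned, and its p-values measure only the spread between arrays.

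For 9 probes the difference between CDM and GM17 in the strain ratio passed that fit, which compares arrays of 1 sample per medium and does not show that the media differ. The log2 ratio of NZ9000 over MG1363 in CDM minus that in GM17 was -2.94 for maa (limma adjusted p 0.000174), -2.42 for apu (0.00741), -2.26 for pepN mg8659 (0.00514), -2.21 for agl (0.00514), -1.94 for glgP mg5208 (0.00807), whose other probes mg8239 (-1.20, 0.213) and mg8240 (-0.87, 0.677) did not pass, -1.72 for amyY (0.00897) and -1.72 for argH (0.00897). It was 2.47 for napC (limma adjusted p 0.00686) and 2.30 for bglA (0.00611). For 8 of the 9, all but amyY, one strain was well above background on only 1 of 2 GM17 arrays, so the sizes of these differences are uncertain. For amyY NZ9000 was 2.20 and 1.59 times its background there, so the size of its difference is uncertain too. For each of the 9 both CDM arrays lay beyond both GM17 arrays. The magnesium transporter gene mgtA, by probe mg5148, was -1.16 in CDM and 0.30 in GM17, with opposite signs on the arrays of the media. The difference of -1.46 did not pass the fit (limma adjusted p 0.0509). For mgtA MG1363 was well above background on only 1 of 2 GM17 arrays, so its GM17 ratio is uncertain too. The probe for lacZ of plasmid pORI280, a gene outside all comparisons, was 1.68 times its background in NZ9000 and 1.69 times in MG1363 in CDM. MG1363 is plasmid-free, so the rule for well above background can pass a probe without its target. On GM17 array 1 it also passed other plasmid and nisin probes in MG1363, among them CmR, nisB and nisC. Ratios that rest on a signal just above background are therefore uncertain in size. With detection set against the plasmid and nisin probes, 56 probes passed the size rule in CDM and 25 in GM17.

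Ratios were smaller in GM17 than in CDM for the 41 probes that passed in CDM and were measured in both, with a median GM17 over CDM ratio of log2 values of 0.520. Plain background subtraction, which adds no offset, gave 0.550, so the offset is not the whole cause. Picking probes on CDM values is not either, since the 24 probes picked on GM17 values had a median CDM over GM17 ratio of 1.35. A slide effect was first tested by asking whether the dimmer GM17 array gave the smaller ratios; it gave 0.625 and the brighter array 0.441, against that idea. The difference of 0.184 between these arrays leaves it open, because slide and medium cannot be told apart. A signal near background in the lower strain may also limit GM17 ratios, which was not tested. For maa NZ9000 was 3.56 and 3.57 times background on the CDM arrays and 1.57 and 1.26 on those of GM17. For apu it was 11.8 and 5.90 against 1.63 and 1.28. Not every probe was that near background. The nrdE probe mg5644 was at least 8.53 times background in both strains and media, with ratios of 1.57 in CDM and 0.75 in GM17. A response to the medium may underlie the pattern too, and its share is unknown.

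The loci numbered after pepN, llmg_0320 to llmg_0325, had a mean of 1.29 in CDM, or 0.84 without napC, against -0.03 for the 6 loci before pepN. Of the 6 loci, 2 passed the size rule (napC and lmrC) and 5 were above 0 on both arrays, while napB was at -0.15 and 1.12. The means of the 2 arrays lay 0.304 to either side of 1.29, first read as excluding array or dye error. A dye effect alone would turn the sign between the swapped arrays, so these values argue against it for the run as a whole. Error of single arrays stays open, because single loci differed in opposite directions. A change at pepN that reaches the following loci may be involved. In GM17 the 5 measured loci had a mean of 0.37, above 97.8% of windows, which was first read as fitting. Without napC the mean was 0.20 (0.202), above 83.8% of windows, so the test left this open. Each window was a mean of 6 measured loci, more than the run had in GM17, so these percentages are not like for like. In CDM 5 of 2124 windows were as high, first read as evidence against chance, but the run was picked for its height.

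Of the values of at least 2-fold in size in the authors' deposited table, 53 of 123 in CDM and 88 of 118 in GM17 were of probes not well above background, as were 9.95% and 43.5% of all its values. Dimness was first judged among values that failed the size rule, which itself leaves out dim probes, so that test was dropped and no explanation was tested.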

How the results depend on the processing

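Settings named in the methods as added were chosen after seeing the data. Each ratio pairs the strains on 1 array, but the labels give 1 sample per medium and no replicate numbers. No test over replicate pairs was therefore possible within a medium. In GM17 53.9% of chromosomal probes were well above background and in CDM 89.7%, so fewer were judged in GM17. Where no cause is shown, the cause was not tested.

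The count over both media (1, malE) was 0 without background correction and with a signal in both strains, 12 with plain subtraction, 11 with median centring, 20 with print-tip loess, 3 without a filter, 2 from the deposited table, 14 to 52 with an array left out, 44 on single arrays and 46 with a dye term. It stayed 1 with Aquantile scaling, which leaves ratios as they are. The malE probe kept its call wherever the count was above 0.

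The CDM count (56) became 132 at 1.5-fold, which a lower threshold must raise, and 123 from the deposited table without a filter; otherwise it was 48 to 83, and 56 to 83 with an array left out. The GM17 count (24) became 13 with a signal in both strains, 38 at 1.5-fold, 118 from the deposited table without a filter and 36 to 104 with an array left out, the 104 without array 2. The difference between media (31) became 16 with a signal in both strains, 58 without a filter, 114 at 1.5-fold, 9 on single arrays and 32 to 152 with an array left out, the 152 without array 2 of GM17. The correlation (0.734) was 0.707 without background correction, 0.775 with print-tip loess, 0.671 with a signal in both strains, 0.593 without a filter, 0.788 from the deposited table, 0.259 without the probes of CDM, and 0.375 to 0.718 with an array left out.

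Of the gene lists outside the random range, 6 of 17 in CDM and 3 of 4 in GM17 stayed there on the same side with each array left out, and of those within it 0 of 8 and 3 of 19 left it. Over no background correction, plain subtraction, median centring and print-tip loess, 15 of 17 and 4 of 4 outside it and 8 of 8 and 16 of 19 within it kept their side; the cell wall list in CDM came within it with median centring (0.099) and print-tip loess (0.063) and multidrug transport without background correction (0.17). Purine metabolism in CDM was -0.087 without array 1 and 0.52 without array 2, and peptide uptake in GM17 was 0.36 without array 1 and -0.11 without array 2. Of 534 recomputed values of named probes, 442 stayed within the SD of the arrays, 92 moved further and 0 changed sign where called. For genes named from lists these numbers were 1282, 1150, 132 and 0, and for list medians 288, 229, 57 and 2. For probes and genes part of this was fixed in advance. Leaving out an array always moves a mean of 2 arrays by less than their SD. A called ratio cannot change sign that way, since both arrays had the called sign. Aquantile scaling leaves ratios as they are.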

Other observations

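The tests in this part were chosen after the results were seen, and the criterion for CodY was tightened after its first outcome. Some genes outside the rule for named genes are given here for their place or function, chosen after their values were seen. The anaerobic ribonucleotide reductase activator gene nrdG (llmg_0282) was at 1.13 ± 0.17 in CDM, numbered next to llmg_0281 at 1.33 ± 0.07, while in GM17 nrdG was at 0.57 ± 0.36. Osmoprotectant transport genes choS and choQ were at 0.68 and 0.65 in CDM and at 0.20 and -0.02 in GM17. Both probes of pbuO, annotated by its symbol among purine uptake genes, had opposite signs in the media, at 0.67 and 0.49 in CDM and -0.74 and -0.70 in GM17. The glutamine synthetase gene glnA was at 0.00 in CDM and -0.97 in GM17. None of these passed the size rule except nrdG and llmg_0281 in CDM.

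The lower maltose, starch and mannitol genes raised the hypothesis of a general lowering of genes for alternative sugars in NZ9000. The 31 measured genes for galactose, nucleosides, ribose, xylose and gluconate had a pooled median of -0.11 in CDM (quartiles -0.21 and -0.02). The mark set for a general lowering was -1. However, 6 and 23 of these genes formed gene lists whose medians had been seen, so the outcome was known when the mark was set. The values show no lowering of that size across these genes, and a smaller one was not tested for the pooled genes. The nucleoside, ribose and xylose list alone, at -0.12, lay below the random range in CDM, but within it without array 2.

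The medians of branched-chain, histidine and glutamate genes in CDM, of which the last 2 came within the random range with an array left out, raised the hypothesis that CodY, the repressor that senses branched-chain amino acids, may be less active in NZ9000. The list of its targets was written from general knowledge, after the medians of the gene lists had been seen. The 17 measured targets not already described had a median of 0.29 in CDM, with 13 of 17 higher on both arrays and array medians of 0.49 and 0.16. This was first read as fitting, but 16 of the 17 belonged to those gene lists, so the test could not decide. In GM17 the 15 measured targets had a median of 0.30, with array medians of -0.13 and 0.63 and 4 of 15 higher on both arrays.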
